A study of Bifidobacterium breve UCC2003 with 2 samples.

How the data were processed

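RNA of Bifidobacterium breve UCC2003, a gut bacterium of infants, was compared between growth on sialic acid and growth on ribose on 2 two-colour Agilent arrays. Each array carried both RNAs, as cDNA labelled with the dyes Cy3 and Cy5. Per the labels, array 1 held ribose RNA in Cy3 and sialic acid RNA in Cy5, and array 2 held them the other way round, a dye swap. The labels do not say whether the arrays held separate cultures or the same RNA extracts. The arrays were therefore treated as n = 2 arrays. Every p-value of a single gene measures only spread between these arrays, with the gene's variance partly pooled over other genes. The p-values of tests over gene lists, gene order or spots rest on genes or spots, and do not measure replication between arrays. The same pair of extracts on both arrays is ruled out by the values: the 4 genes from Bbr_1891 to Bbr_1894 had a median normalized log2 signal of 9.36 in Cy5 of array 1, against 13.42 and 15.08 in the channels of array 2. Whether the other RNA was shared is unknown.

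The deposited spot intensities were made with Agilent Feature Extraction, version 9.5 per the submitters' processing notes and module version 9.1.1.1 per the file headers. Each file gives the mean intensity and the local background intensity of every spot in both dyes. It also gives processed intensities, which are background-subtracted, detrended and dye-normalized per the file headers, and a deposited log10 ratio of Cy5 over Cy3. The deposited value table of the series was identical to that log10 ratio in every row (largest difference 0), with a median of 0 on array 1 and 0 on array 2, so its scale is known and its sign was not turned for the dye swap. Per the series design text, genes were called by the submitters with Cyber-T, a regularised test, at p under 0.001 and an expression ratio beyond 3-fold.

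The design text counts 1864 annotated genes, and 1864 features were tested here: 1843 with a locus tag, 20 tRNA features and 1 16S rRNA feature, with 3 probes per gene in the design of the array. After spots with outlier flags were left out, 16 genes on array 1 and 25 on array 2 had fewer. The other 24 features (plasmid, spike and unassigned probes) were left out of the tests. The files give locus tags without gene names or products. The supplied gene table describes another strain and matched 0 of the tags, and no genome of UCC2003 was supplied. Genes are therefore given by tag, mostly as regions between a first and a last tag, and no coordinates can be stated. Of 26 gene lists fixed before the data were examined, 25 rest on product names and could not be matched, and only the sialic acid locus was tested. Probe sequences were shared with another gene for 6 genes, whose values are uncertain.

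Mean intensities were background-corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, then normalized within each array by loess, with control spots at weight 0. Spots with outlier flags were left out: 81 gene spots on array 1 and 108 on array 2 of 10134. The spots of a probe were averaged, then the probes of a gene. Ratios were turned to sialic acid over ribose by the labelled dyes (sign 1 for array 1, sign -1 for array 2). They were tested against 0 with limma's lmFit and eBayes, which leaves 1 residual degree of freedom per gene before moderation. Moderation added 3.53 prior degrees of freedom as labelled and 2.82 for Cy5 over Cy3 read the same way on both arrays. An SE given for a gene is the moderated one, which rests mostly on variance pooled over genes. Adjusted p-values are Benjamini-Hochberg values over all genes, with a threshold of 0.05. The threshold of the design text (p under 0.001 and over 3-fold) was applied to the same fit. No dye term was fitted, since it would leave no residual degree of freedom. Both arrays came from the same slide and scan per the file headers, so no batch term was possible.

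After the ratios had been seen, a further reading was added: Cy5 over Cy3 taken the same way on both arrays, which is the labelled comparison with the ratio of array 2 turned. Turning array 1 in its place gives the same counts with the directions exchanged. Neither turn is taken as the true one.

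The spread given with a ratio on a single array is the SD over the gene's probes, which is technical. Where a channel was not well above background for any probe of a gene, the fold is a bound, written as at least N-fold. It was computed per array from loess and Aquantile normalized log2 signals. The mean of the bright channel was set against the mean, over probes, of the higher of the dim probe's own signal and the lowest signal among probes well above background in that channel. Such bounds within an array are open to dye bias.

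The genes named follow a rule fixed before the data were examined. It takes the members of the locus, then the 10 genes with the largest and the 10 with the smallest ratio among those past the adjusted threshold with the same direction on both arrays and a signal well above background on both. Where fewer than 5 passed in a direction, it takes up to 5 genes over 3-fold with the same direction on both arrays, described as not having passed. Runs of 3 or more neighbouring tags past the threshold are given as runs where they hold a gene named by that rule. The runs Bbr_0777 to Bbr_0779 and Bbr_1832 to Bbr_1834 hold none, and were added outside the rule. Because the files pair no tag with a name, at most 2 of the genes that were brighter and 2 that were dimmer are printed singly. Regions defined by size on a single array were chosen after their values had been seen.

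The locus was tested with limma's camera at a preset correlation of 0.01, with the estimated correlation as an alternative, and its median was placed among 10000 random lists matched on mean signal. Other alternatives were Agilent's processed signals, no background correction, median centring in place of loess, only probes well above background, the median over spots, an intensity trend with a robust prior, the deposited value table, each array left out in turn, and the methods' t-test (window of 101 genes, 10 prior degrees of freedom). Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

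The fits were tested on simulated data in which 200 of the 1864 genes were changed. Noise was drawn separately for each gene and array at the fitted spread. For the labelled comparison limma recovered 20.9% of genes changed by 1 on the log2 scale, 98.5% of those changed by 2 and 100% of those changed by 4, with 17 false calls. For Cy5 over Cy3 on both arrays it recovered 97.0%, 100% and 100%, with 11 false calls. On the real arrays the ratios shared a part of Cy5 over Cy3 (r = 0.67), which the labelled signs turn into spread. The simulated noise kept the size of that spread but was drawn independently on each array. The shared part is instead opposite on the arrays once the signs are applied. The recovery therefore does not show which changes the labelled comparison could find. The 4 genes from Bbr_1891 to Bbr_1894, with labelled ratios of -3.44 to -1.66, had a limma adjusted p of 0.9996. A simulated list of 12 genes shifted by 2 gave a camera p of 6.12e-10 in the labelled comparison. Its members were picked at random and had separate noise, close to what the preset correlation assumes. The simulated list therefore does not show how camera performs on a run of neighbouring genes.

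The number of arrays limits the precision. Of the gene spots, 30.8% were well above background in Cy3 and 20.8% in Cy5 of array 1, against 41.9% and 41.5% on array 2. Saturation affected 4 spots, in Cy5 of array 2.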

Results

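Transcript levels of Bifidobacterium breve UCC2003 were measured on 2 arrays that each compared a culture grown on sialic acid with a culture grown on ribose. Sialic acid is a sugar that ends many glycans of human milk and of intestinal mucin, and ribose served as the control sugar. Cells were grown without oxygen in modified MRS medium with 0.05% cysteine and 0.5% of either sugar, and harvested at an OD600 of 0.5. A signal well above background in at least 1 channel on both arrays was found for 835 of 1864 genes. At least 1 spot was well above background for 821 genes in Cy3 and 674 genes in Cy5 of array 1, and for 1022 and 1140 genes on array 2.

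The comparison asked which genes change in expression when sialic acid replaces ribose. The genes of the sialic acid locus, Bbr_0160 to Bbr_0172, gave a brighter Cy5 than Cy3 signal on both arrays, although the labels place sialic acid RNA in Cy5 on array 1 and ribose RNA in Cy5 on array 2. The locus is a cluster of nan and nag genes, known for the uptake and breakdown of sialic acid and of N-acetylated amino sugars. The locus was thus higher on sialic acid on array 1 and lower on sialic acid on array 2 when each array was read by its labels. The same held for most of the genome, so the direction of every difference between the sugars is unsettled. Ratios are therefore given per array as log2 of Cy5 over Cy3, beside the comparison as labelled.

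Across the 1864 genes, the Cy5 over Cy3 ratios of the arrays correlated at r = 0.67 (Spearman's rho 0.73), where a dye swap with the labelled dyes gives a negative value for genes that respond to the sugar. Genes are not independent replicates. After the labelled signs were applied the correlation was r = -0.67. Over the 835 genes well above background it was 0.67 before the signs. The ratio had the same sign on both arrays for 1477 genes (79.2%) and opposite signs for 387. Of 42 genes over 3-fold brighter in Cy5 on array 1 and 32 on array 2, 20 were shared, against 0.721 for independent lists. Of 40 and 18 genes over 3-fold dimmer in Cy5, 10 were shared, against 0.386. The normalized signals of Cy3 on the arrays correlated at r = 0.987 across genes and those of Cy5 at 0.898. Channels labelled with the same sugar correlated at 0.859 (ribose) and 0.824 (sialic acid).

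**Figure D1:**
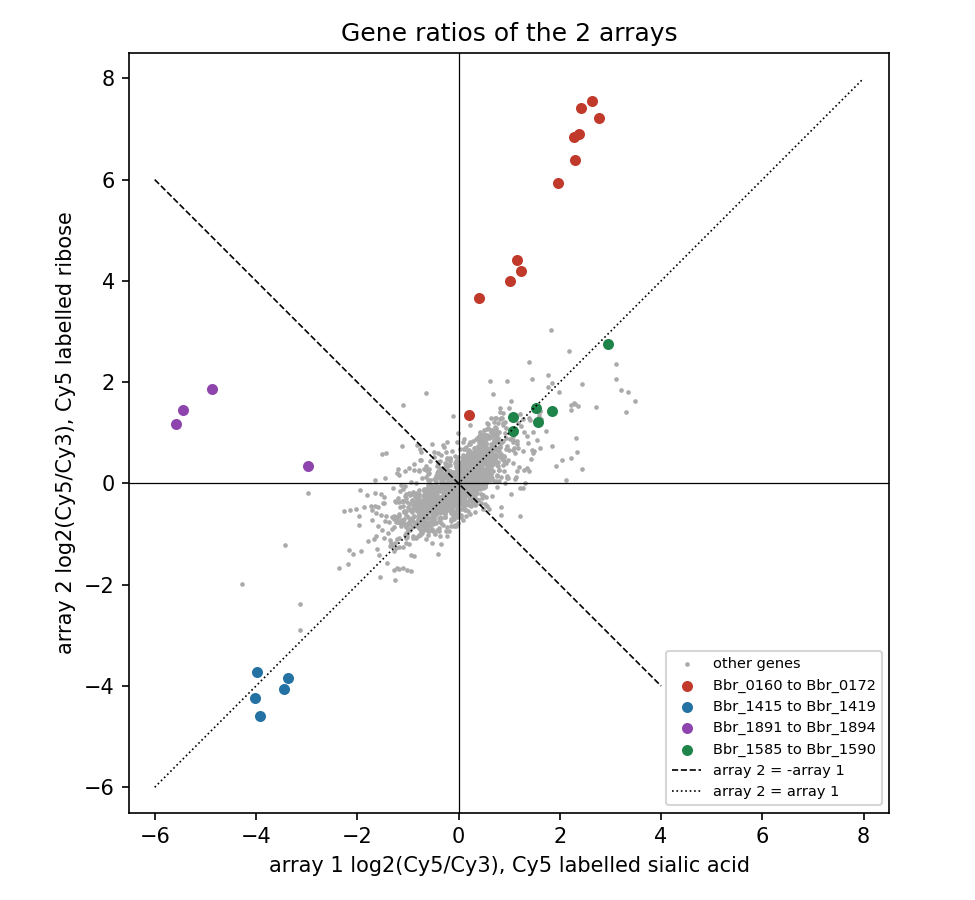
Each point is a gene, with log2 of Cy5 over Cy3 on array 1 (horizontal) and array 2 (vertical); coloured points are 4 gene regions, and the lines mark equal (dotted) and opposite (dashed) ratios. Most genes follow the dotted line (r = 0.67), the locus lies above it, and Bbr_1891 to Bbr_1894 lie at the upper left.

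Of the 13 tags from Bbr_0160 to Bbr_0172, 12 were on the array, and all 12 had positive log2 ratios of Cy5 over Cy3 on both arrays. In the deposited table the ratios of Bbr_0160 and Bbr_0172 on array 1 were 0. Their median was 2.12 on array 1 (range 0.21 to 2.76) and 6.16 on array 2 (range 1.35 to 7.55). The median SD over a gene's probes was 0.15 and 0.44 on the same scale, which is technical spread within an array; the difference in size between the arrays was not tested. The stretch Bbr_0164 to Bbr_0171 held the strongest members, with medians of 2.38 and 6.90. The lowest member on both arrays was the last tag, Bbr_0172. Cy5 was well above background for 9 members on array 1 and for all 12 on array 2, while Cy3 was so for 1 member on array 1 and 0 on array 2. The ratios are thus mostly bounds. On array 1, Cy5 exceeded Cy3 by at least 1.99-fold to at least 6.79-fold in the 8 members with a bound. On array 2 it did so by at least 2.09-fold (Bbr_0172) to at least 109-fold (Bbr_0167).

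**Figure D2:**
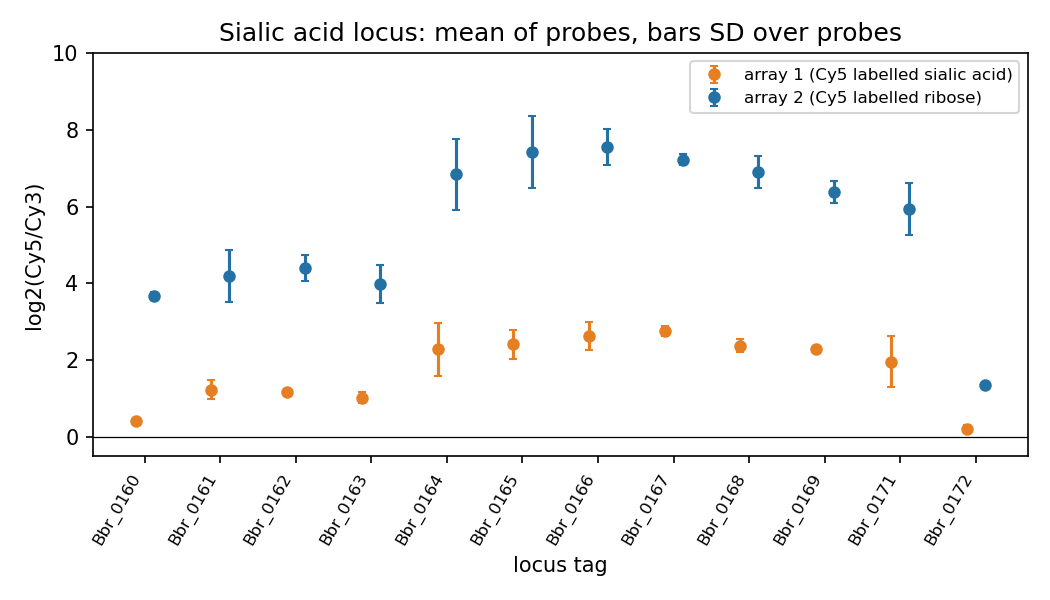
Log2 of Cy5 over Cy3 for the 12 measured genes of the locus, in tag order, on array 1 (orange) and array 2 (blue); points are means over probes and bars the SD over probes. All 12 lie above 0 on both arrays, with medians of 2.12 and 6.16.

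The median of the locus lay above all 10000 random lists of the same size and signal on each array (percentile 100). Those lists held scattered genes, whereas the locus is a run of neighbours. The percentile therefore does not show how rare such a run is. As labelled, the opposite directions were averaged, and the median sialic acid over ribose ratio was -2.01 on the log2 scale (range -2.51 to -0.57), negative because array 2 held the larger ratios. No member passed (0 of 12 with limma after Benjamini-Hochberg adjustment over all genes, and 0 adjusted over the list alone). With the ratio of array 2 turned, the median was 4.14 (range 0.78 to 5.09). Then 0 of 12 members passed over all genes and 10 passed when adjusted over the list alone. Over all genes, 10 passed with Agilent's processed signals and 10 with the methods' t-test, against 0 with the other alternatives. The study may have chosen this locus in part on these arrays, so the list is not taken as independent evidence. With limma's camera, where adjustment over the 1 list tested leaves p as it is, the locus was lower as labelled (adjusted p = 1.39e-12) and higher with array 2 turned (adjusted p = 7.03e-05). Neither call held in limma's camera with an estimated correlation (adjusted p = 0.274 and adjusted p = 0.438). That estimate was 1 in both readings. With 1 residual degree of freedom, members that differ between the arrays in the same direction correlate at 1 whatever their values. The loss of the calls therefore decides nothing. The preset of 0.01 takes neighbouring genes as nearly independent, so its p-values may be far too small and give no firm support either.

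The region Bbr_1415 to Bbr_1419 was dimmer in Cy5 on both arrays to a like extent. Its 5 genes had median log2 ratios of -3.92 on array 1 (range -4.03 to -3.36) and -4.06 on array 2 (range -4.59 to -3.73). The median SD over probes was 0.52 and 0.23. After flagged spots were left out, 1 gene rested on a lone probe on each array. With Cy5 over Cy3 read the same way, all 5 passed the test (median -3.85, limma adjusted p at most 0.0183 after Benjamini-Hochberg adjustment). No call remained without background correction (adjusted p = 0.0876 for all 5 genes), with the intensity trend (adjusted p = 0.0567) or with the deposited table (adjusted p = 0.220). All 5 were called with Agilent's processed signals, whose ratios for these genes equal those of the deposited table. All 5 were also called with median centring, the median over spots and the methods' t-test, and 4 of 4 with only probes well above background. As labelled their mean ratios nearly cancelled, with a median of 0.24. The lowest values were those of Bbr_1418 (-4.25 ± 0.22, moderated SE, limma adjusted p = 0.0173) and Bbr_1419 (-4.13 ± 0.14, moderated SE, limma adjusted p = 0.0164), at n = 2 arrays each. Cy5 was well above background in 1 of the 5 genes on array 1 and in 4 on array 2. Where Cy5 on array 1 gave only a bound, Cy3 exceeded it by at least 9.33-fold to at least 16.3-fold (Bbr_1419).

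Other runs of neighbouring tags were brighter or dimmer in Cy5 on both arrays and passed the same test. Of their 18 genes, 0 were called without background correction, with the intensity trend or with the deposited table. With the median over spots 1 was called, with only probes well above background 4 of 16, and with the methods' t-test 13. All 18 were called with Agilent's processed signals and with median centring. Every gene kept its direction wherever it was measured. The 6 genes from Bbr_1585 to Bbr_1590 were brighter in Cy5, with a median log2 ratio of 1.45 (range 1.06 to 2.85). The highest was Bbr_1590 (2.85 ± 0.14, moderated SE, limma adjusted p = 0.0173, n = 2 arrays). The 3 genes from Bbr_1878 to Bbr_1880 had a median of 2.40, led by Bbr_1880 (2.73 ± 0.23, moderated SE, limma adjusted p = 0.0453, n = 2 arrays). The 3 genes from Bbr_1832 to Bbr_1834 had a median of 1.35. Just before the first of these runs, the 3 genes from Bbr_1582 to Bbr_1584 were dimmer in Cy5, with a median of -1.63. The 3 genes from Bbr_0777 to Bbr_0779 were dimmer, with a median of -1.11. As labelled, none of these runs passed, and the medians of their sialic acid over ribose ratios lay between -0.29 and 0.14.

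The region Bbr_1891 to Bbr_1894 gave opposite ratios on the arrays. Its 4 genes were dimmer in Cy5 on array 1, with a median log2 ratio of -5.15 (range -5.59 to -2.97), and brighter in Cy5 on array 2, with a median of 1.32 (range 0.35 to 1.86). The median SD over probes was 0.16 and 0.10. The 4 genes were the only ones that met the fallback rule for the labelled comparison, with sialic acid over ribose ratios from -3.44 to -1.66 on the log2 scale. None passed after adjustment (limma adjusted p = 0.9996). Cy5 on array 1 was not well above background in any of the 4 genes, and Cy3 exceeded it by at least 7.83-fold to at least 48.0-fold. Bbr_1894 was the only gene over 3-fold in opposite directions on the arrays. The positive ratio of Bbr_1891 on array 2 (0.35) changed sign under median centring (-0.24).

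**Figure D3:**
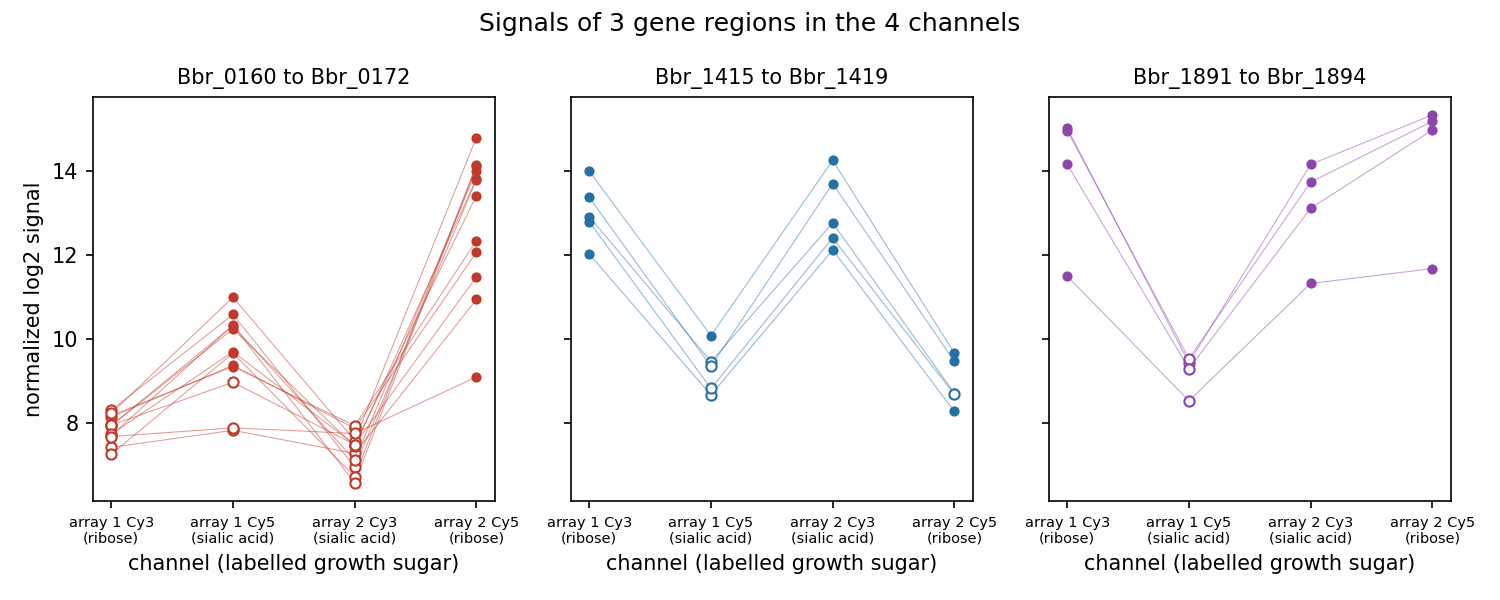
Normalized log2 signal in the 4 channels for the genes of 3 regions, joined by a line per gene; filled points are genes with a probe well above background in that channel, open points are not. Bbr_1415 to Bbr_1419 show the same pattern on both arrays, whereas Bbr_1891 to Bbr_1894 are not well above background in Cy5 of array 1 and bright in the other 3 channels.

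Some regions were over 3-fold on array 1 without reaching it on array 2. The 5 genes from Bbr_1740 to Bbr_1744 were brighter in Cy5, with a median log2 ratio of 2.32 on array 1 and 0.50 on array 2. The 4 genes from Bbr_0436 to Bbr_0439 had medians of -1.90 and -0.34, and the 5 genes from Bbr_1622 to Bbr_1626 had medians of -1.65 and -0.53. The difference between the arrays was not tested.

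As labelled, 0 genes were higher and 0 lower on sialic acid by limma after Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 4 genes, all lower, far below the share of 0.05 that tests without any change would give. The part of Cy5 over Cy3 shared by both arrays stays in the residual of the labelled test. The 0 calls therefore do not show that no gene changed. The intensity trend with a robust prior gave 0 and 0 (0 genes at an unadjusted p under 0.05), and the methods' t-test gave 0 and 0 (4 genes). No gene passed the threshold of the design text in the labelled comparison with limma or with the methods' t-test. With Cy5 over Cy3 read the same way on both arrays, limma called 34 genes brighter and 39 dimmer in Cy5. The 10 genes with the highest ratios among them ran from 1.91 to 2.85 on the log2 scale and the 10 with the lowest from -4.25 to -1.74. The threshold of the design text was passed by 9 brighter and 10 dimmer genes. The counts of that reading depended on the test: the methods' t-test called 108 and 89 after adjustment, and the trend with a robust prior called 0 and 0 (816 genes at an unadjusted p under 0.05).

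Among RNA features, the 20 tRNA features had median log2 ratios of Cy5 over Cy3 of 0.44 on array 1 and 0.24 on array 2, and 14 were positive on both. None was called by limma in either reading. The 16S rRNA feature had ratios of -0.41 ± 0.13 on array 1 and -1.40 ± 0.23 on array 2 (SD over probes).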

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

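The tests below were chosen after the results were seen, except the distance between spots. Probes for genes outside the strain's annotation were not part of any comparison, and some gave signal above the negative controls, of which 2.53% of 79 spots were well above background in Cy5 of array 1. All 6 spots for the OrfX gene of plasmid pBC1 (written pbc1 on the array) were well above background in Cy5 of array 1 (100%), and 0 in the other 3 channels. A feature named only CDS, with 6 spots, was well above background in 66.7% of spots in Cy5 of array 1, 66.7% in Cy3 of array 2 and 100% in Cy5 of array 2, and in 33.3% in Cy3 of array 1. The files do not say what that feature is.

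Over the 3 pBC1 genes, 9 of 17 spots (52.9%) were well above background in Cy5 of array 1. Of these, 6 were spots of OrfX. The 1 spot of copG read 1295 in Cy5 and 422 in Cy3 of array 1, against 98.7 in Cy5 for the other spot of its probe. A raised Cy5 background would lift other foreign probes alike, but 4.85% of 103 other plasmid and spike spots were well above background there (two-sided Fisher's exact test over spots, p = 3.31e-06). Repeated spots of a probe in 1 channel are not independent, so that p-value is too small and measures no replication. Cross-hybridisation with RNA present in every channel would appear in all 4, but the highest share in the other 3 channels was 5.88%. As a hypothesis, the Cy5 extract of array 1 may have held RNA of cells carrying a plasmid related to pBC1, which was not tested. The labels name no plasmid, but for this channel the source name reads UCC200 where the strain tag reads UCC2003, and they do not say whether that is a slip.

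The arrays, labelled as a dye swap, ran the same way. A dye bias independent from gene to gene, as the whole cause with correct labels, would leave neighbouring tags no more alike than random genes. The shared part of Cy5 over Cy3 correlated at 0.587 across 1842 pairs of neighbouring tags (0.456 without 3 regions). Among 100000 permutations of gene order the highest value was 0.103 (one-sided p = 1e-05, the smallest they can give). These values argue only against a bias independent between neighbours. A bias that follows transcript level, or a sugar response of unequal size on the arrays, could also make neighbours alike. The test therefore cannot exclude dye bias in general. Probe base composition took 0.715% of the variance of that shared part, so removing it left the correlation at 0.586 and was no further test. Channels of the same dye were more alike than those of unlike dyes, by 0.101 in mean correlation, but the positive correlation of the ratios already fixes that order, so dyes of a single array recorded the wrong way round and cultures that responded in opposite ways cannot be told apart.

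The region Bbr_1891 to Bbr_1894 and the locus had different ratios on the arrays, a difference that could not be tested against the spread between arrays. Weak Cy5 on array 1 would lose other genes too, but all 88 other genes at least as bright in Cy5 on array 2 as the dimmest gene of Bbr_1891 to Bbr_1894 were well above background in Cy5 of array 1 (100%), against 0 of the 4. A spatial defect would need the 23 spots of that region to lie together, but their median distance was 94.2% of that between gene spots. For the locus, weak or compressed Cy5 was not decided. Ratios of 20 other genes over 3-fold brighter in Cy5 on array 2 differed by a median of -0.26 on the log2 scale. Shrinkage like that of the locus predicts -1.32, so these genes shrank less than predicted. The gap lies within 1 SD, but that SD is over single genes. It is not the error of a median, which was not computed, so the comparison cannot decide. The predicted value takes the locus ratios as measured, although they are mostly bounds, so it is itself uncertain. A mixture of the RNAs of array 1 in Cy5 of array 2 should give signals between its channels. Bbr_1891 to Bbr_1894 had median log2 signals of 14.56 in Cy3 and 9.36 in Cy5 of array 1, against 15.08 in Cy5 of array 2. Bbr_1415 to Bbr_1419 had 12.91 and 9.34, against 8.71. The former would need mostly the Cy3 RNA and the latter almost none, which argues against a mixture for these regions. The locus was brighter in Cy5 of array 2 than in both channels of array 1, by a median of 3.40 on the log2 scale. For the locus this does not decide on a mixture, since the comparison above could not settle whether Cy5 was weak on array 1. Array-to-array variation was not tested.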

How the results depend on the processing

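The reading of Cy5 over Cy3 the same way on both arrays, with all its alternatives, was chosen after seeing the data. As labelled, 0 genes passed in either direction after adjustment or past the threshold of the design text under each of the 8 alternatives. From 0 to 7 genes had an unadjusted p under 0.05. The test was limma's, except in the alternative that used the methods' t-test. Turning array 2 gave 34 and 39 genes after adjustment, 9 and 10 past that threshold, a locus median of 4.14 in place of -2.01, and a camera p of 7.03e-05 in the opposite direction. These reversals follow from the sign itself. Without either array the locus median as labelled ran from -6.16 to 2.12, so array 1 alone reversed it; with a single array left no test was possible, and counts could not be recomputed. Camera kept a lower locus as labelled, with p from 2.74e-27 to 4.94e-05, and lost the call with an estimated correlation (p = 0.274). For Cy5 over Cy3 its p ran from 1.51e-12 to 0.0432, and was 0.438 with an estimated correlation. The estimate was 1 in both readings, which 1 residual degree of freedom forces here, so the lost calls decide nothing.

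The counts brighter and dimmer in Cy5 moved with most settings, and the cause was not tested. After adjustment they were 111 and 155 with Agilent's processed signals, 0 and 0 without background correction (575 genes at an unadjusted p under 0.05), and 240 and 367 with median centring. They were 8 and 7 with only probes well above background (787 genes tested), 1 and 5 with the median over spots, 0 and 0 with the intensity trend, 108 and 89 with the methods' t-test, and 0 and 0 with the deposited table (359 genes at an unadjusted p under 0.05). Past the threshold of the design text they were 53 and 48 with Agilent's processed signals, 6 and 6 without background correction, 4 and 15 with median centring, 0 and 6 with the trend, 17 and 10 with the methods' t-test, and 0 and 4 with the deposited table. Locus members called brighter numbered 10 with Agilent's processed signals and 10 with the methods' t-test, against 0. Of the 73 genes called, Agilent's signals also called 69, median centring 72 and the methods' t-test 51. The sign of all 73 held in every setting that measured all of them, except 72 with median centring. The ratios of named genes on single arrays moved beyond the SD over their probes in 230 cases and stayed within it in 183, leaving out a gene with a lone probe and thus no SD. The sign turned in 1 case, Bbr_1891 on array 2 under median centring (-0.24). Signal over background limits the locus, where Cy3 gave mostly bounds. Each ratio already compares both sugars within an array, so no further block was fitted.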

Other observations

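The 4 genes from Bbr_1898 to Bbr_1901, close in tag order to Bbr_1891 to Bbr_1894, were dimmer in Cy5 on both arrays. Their median log2 ratio was -3.13 on array 1 (range -3.43 to -2.98) and -1.80 on array 2 (range -2.90 to -0.18), and 2 of the 4 passed limma's test with Cy5 over Cy3 read the same way, which like all calls of that reading were lost without background correction, with the intensity trend and with the deposited table. The median SD over probes was 1.16 on array 1, against 0.28 on array 2, so the probes of these genes disagreed on array 1. The region was chosen after its values were seen.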
